A study of Mus musculus with 8 samples.

How the data were processed

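RNA was sequenced from 8 libraries of mouse CD8 T cells, 4 given vehicle (control) and 4 given formate. Naive wildtype cells from spleen and lymph nodes were activated through CD3 and CD28 with interleukin-12 for 18 h, and then received PBS or 2 mM formate for 24 h, per the labels' protocols. Libraries were made with a stranded polyA kit and read as pairs of 58 bp. Trimmomatic, MultiQC and kallisto, and the builds GRCm38 and mm10, are named in the submitters' processing notes without versions. The transcriptome release, the strand setting and any filter are not given in the sources used here.

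The authors deposited one table of estimated counts per gene, which are expected counts summed from transcripts, not normalised and not pooled over replicates. It has 35072 genes, of which 8884 carry no symbol; these were kept under their identifiers and held between 1.22% and 1.65% of the counts of a library. Of the identifiers, 34581 are in GENCODE M21 (GRCm38), which supplied coordinates, GC content and transcript length. Of the non-zero values 56.7% were not whole, and all were rounded to whole numbers before testing. Library totals ranged from 29361986 to 41393093 counts. Counting noise is therefore small for all but the lowest genes, and 3 counts in the smallest library equal 0.102 CPM. Reads of near-identical genes (ribosomal protein and glycolytic genes with processed pseudogenes, paralogs such as Lilrb4a) are divided between copies by the estimate, and their values are uncertain to that extent. Antisense and overlapping genes are uncertain too, because the strand setting is not given.

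Groups were taken from the treatment label, and replicates were numbered in accession order, which only names them. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. No pair of libraries of a group differed by as little as sampling noise: the smallest chi-square per degree of freedom over genes was 22.2.

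Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, robust quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which left 13299 genes. CPM values are TMM-normalised, with mean ± SD over 4 libraries. The design, the named-gene rule, the gene lists and most alternative settings were chosen before the data were examined. The planned comparison has no pairing term (the unpaired fit). The titles carry codes that run in neighbours (1 and 2, 7 and 8, 10 and 11, 13 and 14), each pair holding 1 control and 1 formate library, but no label states that neighbours belong together. A rule set in advance asked for the fit with these pairs as a replicate block (the paired fit) wherever it changes a call, if deviations from the group means correlated over 0.1 in every pair. The correlations were 0.653 for codes 1 and 2, 0.369 for 7 and 8, 0.656 for 10 and 11, and 0.370 for 13 and 14. Of the 8 libraries, 7 correlated best with their neighbour among the libraries of the other group. Control 4 reached 0.369 with its neighbour and 0.373 with formate 3. The best non-neighbours reached 0.270 to 0.373, also over the bound, and were of the same library set (codes 1 to 8 or 10 to 14). The bound therefore does not by itself tell pairs from library sets. The pairing comes from the title codes and not from a stated design. Only for codes 1 and 2 and for 10 and 11 did the correlation lie well above that within a set.

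Gene lists, 43 in number, were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2, Benjamini-Hochberg over the lists); 41 had at least 4 tested members. The erythroid and platelet list and the stromal list did not, and their summed CPM is given instead. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, one way and does not compare the list with other genes. Single measures per library were compared by exact two-sided permutation tests over the 70 assignments, for which the smallest possible p is 0.0286.

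The named genes are a fixed panel of 20 genes; the 6 largest increases and 6 largest decreases among called genes with a mean of at least 5 CPM and group ranges that do not overlap; up to 4 called members of each list past its threshold, by smallest p; and, where fewer than 3 genes passed in a direction, the 3 smallest p in that direction. Genes without a symbol, or with symbols of Gm plus digits or ending in Rik, were left out of the picks by largest change and by smallest p in a direction. The rule was applied to both fits. Srxn1, Tkt, Pgd, Esd, Iigp1, Ifi47, Tap1, Psmb8, Asns, Slc6a9, COX1, CYTB, ND3 and the genes of the interaction test were named after their values had been seen. The list of genes with detained introns was drawn up after the data had been examined, because 5 genes of that kind stood among the calls; those 5 were left out, and the values of the listed genes had not been seen. Single values of a few genes that belong to the named set are not reported here.

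The fits were tested on simulated data with 200 changed genes, in 5 simulations of the comparison with about 13071 genes. The simulated means were averages of each neighbouring pair and the spread came from the paired design, so neighbours were pairs by construction. The shares recovered and the shares of false calls thus hold only if neighbours are pairs, and do not test the pairing. With gene-wise spread the paired fit recovered 52.5% of genes changed 1.25-fold, 72.4% at 1.5-fold, 84.4% at 2-fold and 95.5% at 3-fold. The unpaired fit recovered 0%, 15.4%, 48.0% and 69.1%. Of the paired calls 9.27% were false (4.58% to 13.5% over simulations), above the nominal 5%, and none of the 323 unpaired calls was. A simulation with trended spread was added after that result, and gave 3.91% false paired calls. In both fits camera called a simulated list shifted 1.25-fold and 0 of 40 unshifted lists. The simulated genes were drawn independently of each other, so this does not test camera on lists whose members move together. In the real data the estimated correlation was 0.62 for the glycolysis list in the unpaired fit. Over the 14 lists that camera called in the paired fit it ran from 0.03 (cytotoxic and Tc1 effector) to 0.94 (ribosome biogenesis and MYC targets), again estimated in the unpaired fit.

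Alternatives were other size factors (RLE, upper quartile, library size only), filters, DESeq2 1.42.0, limma-voom, non-robust dispersion, a 1.2-fold minimum, each library left out, and for lists the prior count. Added after seeing the data were the library set (codes 1 to 8 against 10 to 14) as a term, each set alone, the pairs as a random effect, and, in the paired fit, each pair left out, GC or length offsets per library and counts thinned to the smallest library. GC content and length were available for 99.3% of tested genes. Nuclear copies of mitochondrial genes were sought with BLAST+ 2.17.0. The paired fit without a filter on low counts called 2277 of 23059 genes, but its estimated prior degrees of freedom were infinite, so every gene took the trend's spread; it was left out of the alternatives. All other edgeR fits had finite values, with a median of 12.7 in the paired fit and 2.87 in the unpaired fit.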

Results

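The series measured gene expression in activated mouse CD8 T cells exposed to formate, a one-carbon metabolite that cells also make from serine. Naive cells were activated for 18 h with antibodies to CD3 and CD28 and with interleukin-12, which drives the type 1 cytotoxic programme, and were then kept for 24 h with 2 mM formate or PBS. Each group had 4 libraries. Controls 1 to 4 held 35954496, 41393093, 37102527 and 30275374 estimated counts, and formate libraries 1 to 4 held 29361986, 36748663, 38010357 and 30389825. The series title ties the work to an exercise-induced microbial metabolite and antitumour immunity; the comparison asks how formate changes the transcriptome of these cells.

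The largest axis of variation did not separate formate from control. PC1 held 51.2% of the variance, split the libraries with title codes 10 to 14 from those with codes 1 to 8, and gave an exact permutation p of 0.8 between groups of n = 4. PC2 held 12.4% and was lower with formate in 4 of 4 pairs (exact permutation p = 0.0286, the smallest this test allows). PC3 gave an exact permutation p of 0.629, and the p values were not adjusted over the components. The test treats all libraries as interchangeable, which the correlation within pairs goes against. Swaps within pairs allow no p under 0.125, so the separation on PC2 is descriptive. The fixed CD8 T cell identity genes gave 3576 ± 230 CPM in controls and 3497 ± 109 CPM with formate (SD, n = 4, exact permutation p = 0.686). Markers of other cells were compared in the same family of 11 measures, in which the smallest exact permutation p, 0.0286, adjusts to 0.314 for a single measure, so none could pass alone. B cell markers were at 182 ± 6.24 and 172 ± 5.36 CPM (lower in 4 of 4 pairs, exact permutation p = 0.0857), CD4 T cell markers at 16.6 ± 3.25 and 15.2 ± 4.56, NK and innate lymphoid markers at 10.1 ± 5.12 and 8.34 ± 3.39, and myeloid and dendritic markers at 125 ± 43.1 and 120 ± 31.7. Erythroid and platelet markers were at 1.10 ± 0.184 and 1.64 ± 0.364 CPM (higher in 4 of 4 pairs, exact permutation p = 0.0571), and stromal markers at 20.3 ± 3.07 and 20.8 ± 2.78. Sums and single genes differed in direction for B cell markers, whose median log2 change over 10 genes was 0.03 (higher in 3 of 4 pairs; 1 gene rose and 0 fell in the paired edgeR fit), and for myeloid and dendritic markers (median 0.09). The median was -0.06 for CD4 T cell markers and -0.21 for NK and innate lymphoid markers, and none of these 4 lists passed camera.

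**Figure D1:**
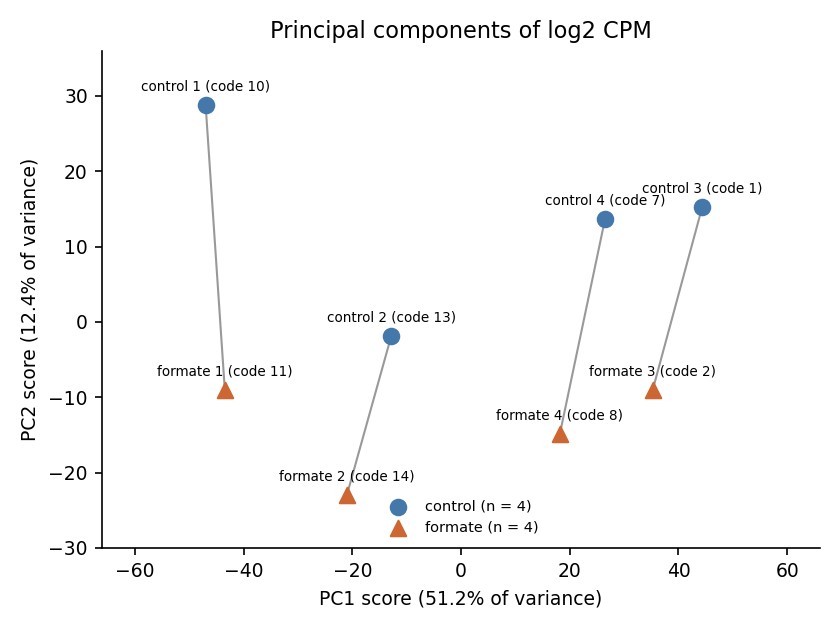
PC1 and PC2 scores of log2 CPM for the 4 control (circles) and 4 formate (triangles) libraries, with lines joining neighbouring title codes. PC1 (51.2% of variance) follows the library sets, and each formate library lies below its neighbouring control on PC2 (12.4%).

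Cth, the cystathionine gamma-lyase of the transsulfuration pathway that makes cysteine, rose with formate from 15.1 ± 2.27 to 38.0 ± 2.60 CPM (SD, n = 4; log2 change 1.33, SE 0.12). The gene (ENSMUSG00000028179) lies on chromosome 3 from 157894248 to 157925077 (GRCm38). Every formate library lay above every control. Cth was the 1 gene of 13299 past the threshold in the unpaired fit (edgeR adjusted p = 0.0212; 634 genes had a raw p under 0.05, 0 genes fell, and DESeq2 called 11 higher and 10 lower). In the paired fit its change was 1.33 (SE 0.08, edgeR adjusted p = 2.37e-06). The unpaired call was lost without control 2, 3 or 4 or any 1 formate library (adjusted p between 0.0820 and 0.214) and kept without control 1 (0.00528). The log2 change stayed between 1.254 and 1.43 there, and was 1.499 within codes 1 to 8 (adjusted p = 0.136) and 1.17 within codes 10 to 14 (0.911).

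By the named-gene rule, the next increases in the unpaired fit by smallest p did not pass: Calcrl, a receptor subunit for calcitonin-family peptides, had a log2 change of 0.67 (SE 0.11) and Cdc37l1, a co-chaperone gene, one of 0.38 (SE 0.07), both with an edgeR adjusted p of 0.711. Of the decreases, Ccnd3 (cyclin D3) had -0.31, Rnpep (an aminopeptidase) -0.26 and Arhgap19 (a GTPase-activating protein) -0.28, each with an adjusted p of 0.998. All 5 passed with the pairs as a block, with edgeR adjusted p values of 0.00126, 0.00167, 0.00173, 0.00346 and 0.00496.

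With the pairs as a block 1711 genes passed (edgeR, 3761 with a raw p under 0.05), 711 higher and 1000 lower with formate, most by small amounts: the median size of the log2 change among them was 0.22, and 98 changed more than 1.5-fold. The same direction held in all 4 pairs for 1680 of them. Group ranges did not overlap for 307 of them. Over all tested genes this held for 4.29%, where chance gives 2.86% if all 8 libraries are interchangeable, which the correlation within pairs goes against. Genes without a symbol or with Gm or Rik symbols were left out of the ranking that follows. Beside Cth and Calcrl (8.26 ± 0.821 to 13.1 ± 0.684 CPM), the largest increases with separate ranges among genes with a mean of at least 5 CPM were Lilrb4a (ENSMUSG00000112148, an inhibitory receptor with a near-identical paralog, so its value is uncertain), which rose by 0.63, Ankrd16 (0.53), Ints6l (0.52) and Zfp950 (0.50). Nqo1, below that mean, rose by 0.87. The largest decreases by the same rule were Lmna (lamin A/C, -0.47), Atp5mc2 (a subunit of ATP synthase, -0.37), Ttc21b (-0.35), Tars3 (a threonyl-tRNA synthetase, -0.35), Eid2 (-0.33) and Mzt2 (-0.32). The edgeR adjusted p of these 10 genes lay between 0.00126 (Ankrd16) and 0.0354 (Eid2). With GC offsets the Zfp950 change shrank from 0.50 to 0.28 (SE 0.10 and 0.09, adjusted p = 0.0764), whereas Eid2 went from -0.33 to -0.29 (SE 0.10 and 0.09) and missed the threshold with 0.0655.

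Balance and number of the paired calls moved with the scaling and the pairs used. Against 711 higher and 1000 lower, upper quartile scaling gave 832 and 736, library size only 1048 and 539, DESeq2 492 and 1082, and GC offsets 422 and 962. Genes that rose had a median transcript GC content of 44.1% and genes that fell 52.8%, where all tested genes had 49.6%. Without codes 1 and 2 the count was 337, without 7 and 8 it was 722, without 10 and 11 it was 1371 and without 13 and 14 it was 502. Of the 76 named genes called with the block, 33 kept the call without codes 1 and 2, 61 without 7 and 8, 69 without 10 and 11 and 48 without 13 and 14. In simulated data with gene-wise spread, where neighbours were pairs by construction, 9.27% of paired calls were false. Against a 1.2-fold minimum 6 genes passed, 5 higher and 1 lower. The counts of list members given below stand beside 711 higher and 1000 lower among all 13299 tested genes.

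Of 19 tested glycolytic genes 11 fell with formate, 0 rose and 8 did not pass in the paired edgeR fit; adjusted over the list alone 14 fell. Gapdh went from 4699 ± 1281 to 3813 ± 765 CPM (log2 change -0.28, SE 0.05), and Pfkl (phosphofructokinase, -0.28), Hk1 (hexokinase 1, -0.27) and Eno1 (enolase, -0.28) fell with adjusted p values between 0.00259 and 0.00539. In the TCA cycle 7 of 20 members fell, 0 rose and 13 did not pass (10 fell adjusted over the list alone). Among these were Sdha (a succinate dehydrogenase subunit, 269 ± 34.2 to 213 ± 30.2 CPM, -0.34), Dlat (-0.25) and Pdha1 (-0.17) of pyruvate dehydrogenase, and Suclg2 (-0.18). The list medians were -0.19 and -0.13. Camera gave adjusted p values of 0.0139 and 0.00131 unpaired and 6.47e-05 and 0.00144 paired, but 0.948 and 0.913 (unpaired) and 0.838 for both (paired) with an estimated correlation. The unpaired glycolysis call was lost without control 1 (median -0.023, adjusted p = 0.528), control 2 (-0.11, 0.132), formate 3 (-0.060, 0.540) or formate 4 (-0.14, 0.107), and its median was -0.36 without control 3 and -0.32 without formate 1. The TCA cycle call was kept without any 1 library, with a median of -0.080 without formate 1. The decreases in the glycolysis, TCA cycle, lipid synthesis, cell cycle and ribosome biogenesis lists came with a higher mitochondrial share of counts (0.462% to 0.702%, higher in 4 of 4 pairs). Their sizes matched by pair for only some lists. The median of mitochondrially encoded genes was highest for codes 10 and 11 (1.10), where the TCA cycle, cholesterol, G1/S and G2/M medians were lowest. Ribosome biogenesis fell least there (-0.01), and glycolysis (-0.29) and fatty acid synthesis (-0.14) fell more in another pair. In the paired fit 21 genes known for isoforms with detained introns, which stay in the nucleus, had a median change of 0.10. With the GC trend removed it was 0.06. The first value was at percentile 99.99 of random lists matched on expression, which treat genes as independent. Of the 21 genes 8 rose, 0 fell and 13 did not pass, and the counts do not separate these isoforms from spliced mRNA. The list was drawn up after 5 other genes of its kind had been seen among the calls.

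Of 21 cholesterol synthesis genes 9 fell, 0 rose and 12 did not pass (10 fell and 2 rose adjusted over the list alone), including Fdps (-0.25), Dhcr7 (-0.21) and Mvk (-0.27), which are enzymes of the pathway. Of 13 fatty acid synthesis genes 6 fell, 0 rose and 7 did not pass (8 fell adjusted over the list alone). Fads2 (a desaturase, -0.37), Scd2 (-0.22), Srebf1 (the lipogenic transcription factor, -0.18) and Acly (ATP citrate lyase, -0.17) were among them. The 2 lists passed camera in the paired fit (adjusted p = 0.00998 and 0.00144; 0.838 for both with an estimated correlation), not in the unpaired fit (0.234 and 0.167). The cholesterol call was lost without codes 1 and 2 (0.0808), the fatty acid median was -0.11 without 13 and 14 against -0.17, and the Acly call with GC offsets (0.0527), where its change was -0.15 (SE 0.05 in both).

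Of 21 G2/M and mitosis genes of the cell cycle 9 fell, 0 rose and 12 did not pass (11 fell adjusted over the list alone). The kinase gene Plk1 went from 161 ± 20.7 to 127 ± 20.1 CPM (-0.35, edgeR adjusted p = 0.00124), and Ube2c (-0.26), Ccna2 (cyclin A2, -0.23) and Tpx2 (-0.24) fell as well. Of 23 G1/S genes 8 fell, 1 rose and 14 did not pass (9 fell and 1 rose adjusted over the list alone): Mcm3 (-0.22) and Mcm2 (-0.19) of the replicative helicase and Pola1 (-0.26) fell, and Ccne2 (cyclin E2) rose by 0.27. With GC offsets Ccne2 had 0.06 and no longer passed. Camera gave G2/M an adjusted p of 0.00131 unpaired and 0.00144 paired, and G1/S 0.0775 and 0.0477. With an estimated correlation the adjusted p was 0.783 (G2/M, unpaired), 0.948 (G1/S, unpaired) and 0.838 for both lists in the paired fit. The G1/S call was lost without codes 1 and 2 (0.0617), 7 and 8 (0.167) or 10 and 11 (0.0530) and with library size only (0.0744).

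Of 24 ribosome biogenesis and MYC target genes 7 fell, 1 rose and 16 did not pass (12 fell and 1 rose adjusted over the list alone). Ncl (nucleolin) went from 3446 ± 1082 to 2617 ± 827 CPM (-0.40, edgeR adjusted p = 0.000799), and Ddx21 (-0.24), Rrp12 (-0.22) and Fbl (fibrillarin, -0.21) fell. Of 80 ribosomal protein genes 12 rose, 1 fell and 67 did not pass (16 and 1 adjusted over the list alone), Rps12 by 0.26, Rpl22l1 by 0.26, Rps25 by 0.24 and Rpl5 by 0.20. Camera gave adjusted p values of 0.00196 and 0.00998 in the paired fit and 0.271 and 0.296 in the unpaired fit. With an estimated correlation the paired adjusted p was 0.838 and 0.865, and the ribosomal protein call was lost without codes 1 and 2 (0.0617) or 13 and 14 (0.246, median 0.020 against 0.061 with all pairs and 0.10 without 10 and 11). The size of the ribosomal protein change also moved with the scaling, with a median of 0.097 in the paired fit with library size only.

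Of 24 cytotoxic and Tc1 effector genes 5 rose, 0 fell and 19 did not pass (6 rose adjusted over the list alone; median 0.08). The chemokine genes Xcl1 (531 ± 275 to 653 ± 302 CPM, 0.33) and Ccl4 (0.27), Klrd1 (a lectin-like receptor, 0.29) and Srgn (serglycin, the granule proteoglycan, 0.21) rose, with edgeR adjusted p values between 0.00222 and 0.00745. With GC offsets Klrd1 had 0.07 and no longer passed. The hallmark effectors did not pass in either fit: in the paired fit Ifng had 0.13 (SE 0.06, adjusted p = 0.142), Gzmb 0.06 (0.556), Prf1 0.06 (0.569) and Tnf 0.08 (0.359). Of 18 type 1 transcription factor and interleukin-12 receptor genes 3 fell, 1 rose and 14 did not pass (3 and 1 adjusted over the list alone): Stat4 (-0.28), which signals from the interleukin-12 receptor, Eomes (-0.28) and Bhlhe40 (-0.18) fell, and Il18r1 rose by 0.21. Tbx21 (-0.10, 0.128) and Il12rb2 (-0.18, 0.183) did not pass.

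Camera gave these lists paired adjusted p values of 0.0392 (effector) and 0.0153 (transcription factor), 0.838 for both with an estimated correlation, and 0.532 and 0.167 in the unpaired fit. The effector call was lost without codes 7 and 8 (0.0603), 10 and 11 (0.0530) or 13 and 14 (0.283) and with the GC trend removed (0.149, median 0.075 against 0.076), and the transcription factor call without codes 1 and 2 (0.0566). Of 10 STAT5 targets 3 fell, 0 rose and 7 did not pass, with the same count adjusted over the list alone: Bcl2l1 (-0.19), Il2rb (-0.20) and Pim2 (-0.18). Their camera adjusted p was 0.0477 paired, 0.212 unpaired and 0.838 with an estimated correlation, and was lost without codes 1 and 2 (0.205, median -0.058), 7 and 8 (0.167) or 13 and 14 (0.0918), with RLE size factors (0.0520), with library size only (0.0744) and with the GC trend removed (0.192, median -0.089 against -0.092). Pdcd1 (0.14, 0.0762), Il2ra (0.02, 0.861), Cd8a (0.00, 0.973) and Tcf7 (-0.10, 0.134) did not pass in the paired edgeR fit.

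**Figure D2:**
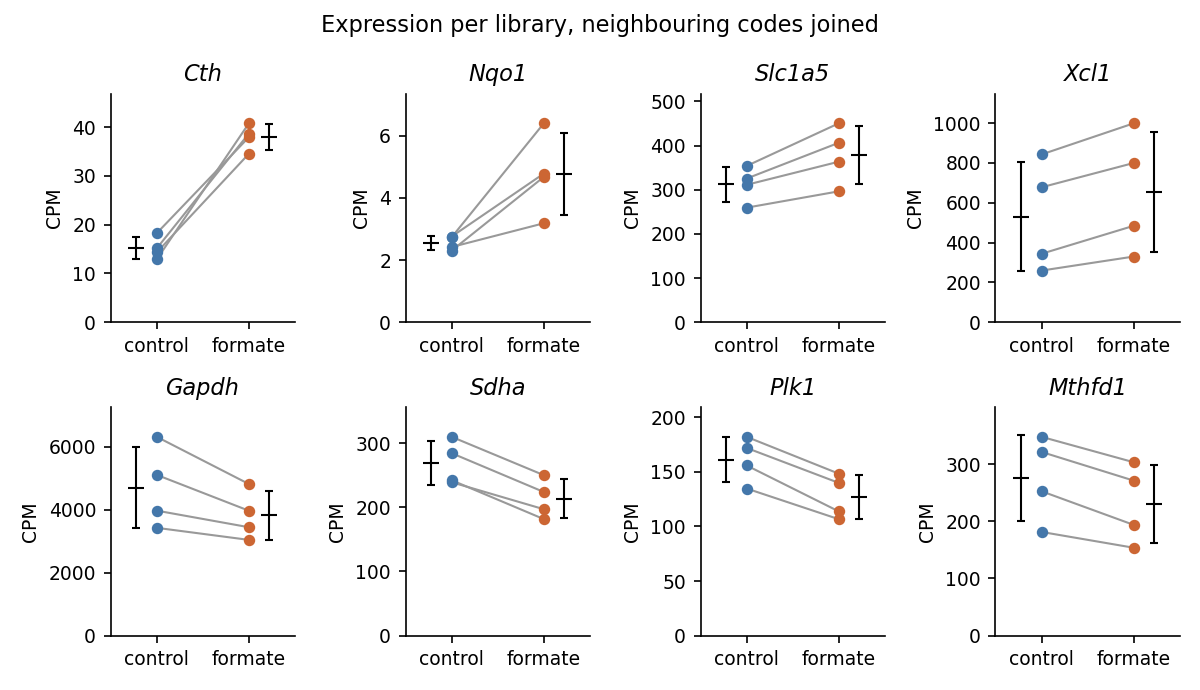
CPM per library of 8 genes (control left, formate right), with lines joining neighbouring title codes and bars giving mean ± SD (n = 4 per group). Cth separates the groups (15.1 ± 2.27 and 38.0 ± 2.60 CPM), while for Xcl1 the shift within pairs is small beside the spread between pairs.

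Formate is a one-carbon unit donor, and the folate, serine and purine lists were included for that reason. Of 26 folate one-carbon genes 2 rose, 1 fell and 23 did not pass, with the same count adjusted over the list alone (camera adjusted p = 0.502 unpaired and 0.522 paired). Mthfd1, the cytosolic enzyme that takes formate onto tetrahydrofolate, fell from 276 ± 74.6 to 230 ± 68.8 CPM (-0.27, SE 0.05, edgeR paired adjusted p = 0.00368). Esd (S-formylglutathione hydrolase, 0.31, 0.00261), chosen after its values were seen, rose. Mthfd2 (0.03, 0.878), Shmt2 (0.05, 0.683) and Aldh1l2 (1.43, SE 0.57, 0.237) did not pass. Mthfd2 and Shmt2 were higher with formate in 2 of 4 pairs each, and the direction followed the library set. For the pairs of codes 1, 7, 10 and 13, Mthfd2 had log2 changes of 0.28, 0.26, -0.27 and -0.13. Shmt2 had 0.25, 0.21, -0.14 and -0.12, and Aldh1l2, higher in 4 of 4 pairs, had 2.11, 3.13, 0.36 and 0.999. The edgeR interaction with the library set did not pass for Mthfd2 or Aldh1l2 (adjusted p = 0.0851 for both).

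Of 9 serine synthesis and transport genes 2 rose, 0 fell and 7 did not pass, with the same count adjusted over the list alone: the glutamine and serine transporter gene Slc1a5 (312 ± 39.6 to 379 ± 65.6 CPM, 0.27) and Srr (serine racemase, 0.46). The median was 0.27, with a camera adjusted p of 0.00596 unpaired and 0.0477 paired, but 0.783 and 0.838 with an estimated correlation; the paired call was lost without codes 1 and 2 (0.114, median 0.14) or 7 and 8 (0.167, median 0.26) and with library size only (0.0556). The list median was 0.35 for codes 1 and 2, 0.33 for 7 and 8, 0.01 for 10 and 11 and 0.18 for 13 and 14. The unpaired call was lost without formate 3 (median 0.20) or formate 4 (0.24), with an adjusted p of 0.0706 in both. The Srr call was lost with GC offsets (0.0506), although its change hardly moved (0.46 to 0.45, SE 0.14 in both). Of 14 purine synthesis genes 6 fell, 2 rose and 6 did not pass (7 and 2 adjusted over the list alone). Gmps (-0.25), Gart (-0.22), Impdh2 (-0.21) and Ppat (-0.19) of the de novo pathway fell, with edgeR adjusted p values between 0.00447 and 0.0138. The purine list had a camera adjusted p of 0.158 unpaired and 0.0477 paired (0.838 with an estimated correlation), lost without any of the pairs (0.0530 to 0.0910) and with library size only (0.0714).

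NRF2 target genes, included because NRF2 is the antioxidant regulator tied to formate in what is known of the study, did not pass as a list. The median was 0.01, the camera adjusted p 0.762 unpaired and 0.598 paired, and of 27 members 2 rose, 3 fell and 22 did not pass (3 rose and 3 fell adjusted over the list alone). Nqo1, a quinone reductase, rose from 2.55 ± 0.227 to 4.76 ± 1.31 CPM (0.87, SE 0.16, edgeR paired adjusted p = 0.00426; 0.998 unpaired). Srxn1 (sulfiredoxin) rose by 0.55, and the pentose phosphate enzyme genes Tkt (-0.23) and Pgd (-0.25) fell; these 3 were chosen after their values were seen. Nfe2l2, which encodes NRF2, had -0.10 (0.188), Keap1 -0.11 (0.111), Gclm 0.12 (0.236), Hmox1 0.36 (0.288) and Slc7a11 0.95 (SE 0.77, 0.525). The last 2 genes differed between pairs. For the pairs of codes 1, 7, 10 and 13, Slc7a11 had log2 changes of 2.48, 2.31, -0.60 and 0.06, and Hmox1 had 0.84, 0.70, -0.23 and 0.19. The edgeR interaction with the library set, chosen after the data were seen, passed for Slc7a11 (adjusted p = 0.00125).

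The 13 mitochondrially encoded genes had a median log2 change of 0.57 and a camera adjusted p of 4.01e-11 unpaired and 6.47e-05 paired, but 0.783 and 0.838 with an estimated correlation. With the GC trend removed, the median of these genes in the paired fit shrank to 0.42 (camera adjusted p = 0.0013). None of them passed alone in the paired edgeR fit, over all genes or adjusted over the list alone; in the unpaired fit 0 passed over all genes and 9 were higher adjusted over the list alone. COX1 (1706 ± 255 to 2582 ± 695 CPM, 0.57, SE 0.13) had a paired adjusted p of 0.0629 and CYTB (545 ± 80.6 to 828 ± 97.0 CPM, 0.61) one of 0.0953. Both passed with the block in DESeq2 (0.0422 and 0.00868), limma-voom (0.00955 for both) and edgeR without robust estimation (0.0133 for both). ND3 was at -0.03. These 3 genes were chosen after their values were seen. The mitochondrial share of counts was 0.462 ± 0.0705% in controls and 0.702 ± 0.152% with formate, higher in 4 of 4 pairs (exact permutation p = 0.0571, adjusted 0.314, in a family where no single measure could pass alone). Nuclear respiratory chain genes did not pass as a list (median 0.04, camera adjusted p = 0.766 unpaired, where its direction was down, and 0.726 paired; 4 rose, 5 fell and 28 did not pass, and 6 rose and 7 fell adjusted over the list alone).

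**Figure D3:**
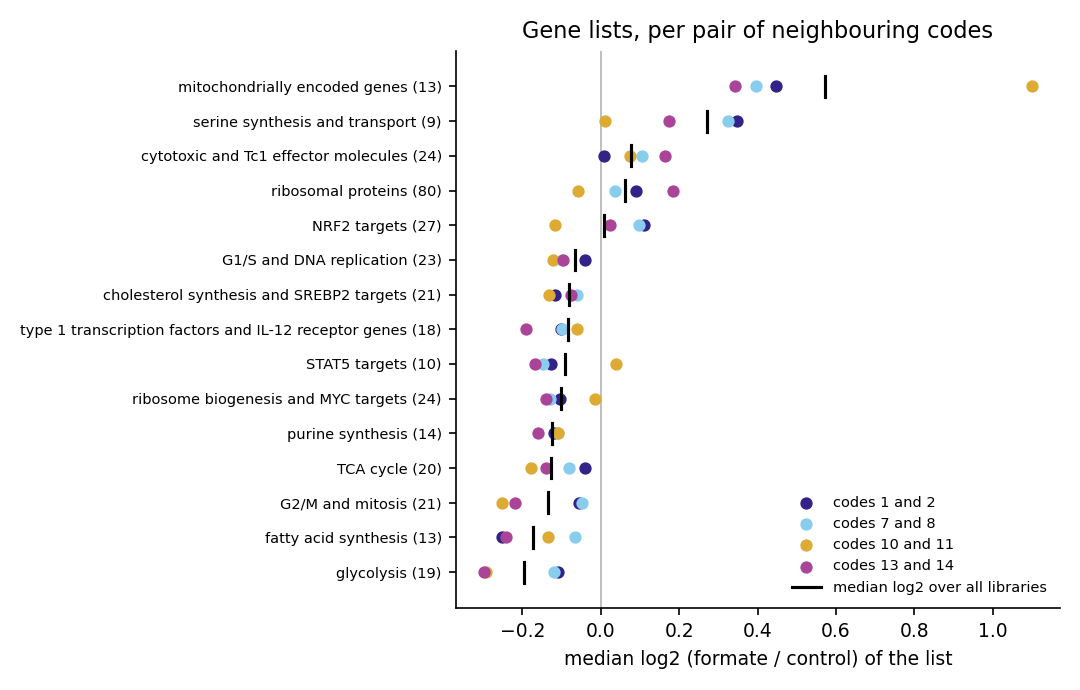
Median log2 (formate / control) of the 14 gene lists past the threshold in the paired fit and of the NRF2 targets, for each pair of neighbouring codes (points) and over all libraries (bars), with the number of tested genes in brackets. Glycolysis lies below 0 in all 4 pairs (median -0.19) and mitochondrially encoded genes above 0 in all 4 (0.57).

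In all, 5 lists passed camera unpaired and 14 paired, the 5 among them, and 27 of 41 passed in neither fit. With an estimated correlation 0 lists passed in either fit (smallest adjusted p 0.783 unpaired and 0.838 paired), and fry called 0 unpaired and 1 paired. That 1 was the methionine and polyamine list (0.0257), which holds Cth and whose median (-0.02) and mean (0.08) differ in sign. Lists as many as the 5 unpaired calls were also found in 26 of the 35 ways to split the 8 libraries into 4 and 4, the real one included. ATF4 targets, the amino acid response genes, did not pass as a list (camera adjusted p = 0.0775 unpaired and 0.181 paired), with a median log2 change of 0.09. Asns (asparagine synthetase), chosen after its values were seen, had paired log2 changes of 2.08 for codes 1 and 2, 1.79 for 7 and 8, 0.26 for 10 and 11 and 0.89 for 13 and 14. Its paired edgeR adjusted p was 0.189, but it passed with DESeq2 (0.0154), limma-voom (0.0129) and without robust estimation (0.0152).

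**Figure D4:**
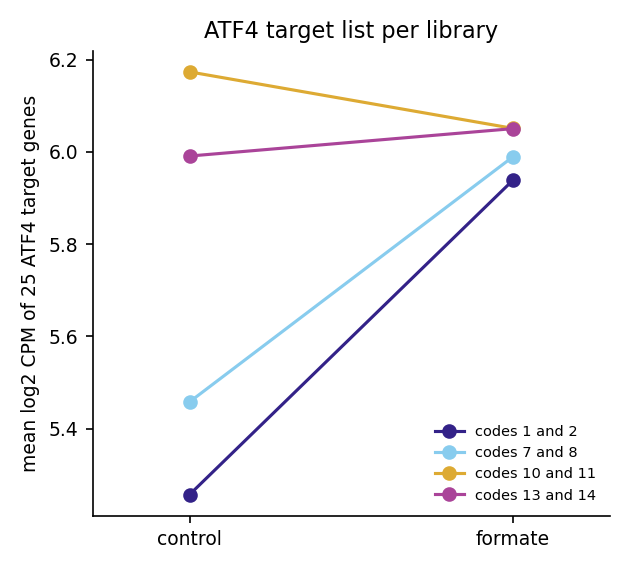
Mean log2 CPM of the 25 ATF4 target genes in each library, with lines joining neighbouring title codes; the axis does not start at 0. Controls range from 5.26 to 6.17 and formate libraries from 5.94 to 6.05.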

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

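The test of GC-corrected genes with detained introns, the test of ATF4 levels in formate against control libraries, its allowance for the number of lists, the comparison of changes before and after GC offsets and the interaction with the library set were chosen after the result was seen; the other tests were planned before theirs. The list of genes with detained introns was drawn up after 5 other genes of that kind had been seen among the calls, and leaves those 5 out; the values of its members had not been seen. Of 222 groups of 4 libraries, 10 held 1 library so far from the rest that its gap to the nearest one, divided by the range, passed the 95% critical value of Dixon's test; chance gives about 1 in 20. By gene these were Calcrl in control 1 (9.48 CPM, the others at most 7.97, ratio 0.841), Rpl5 in control 3 (57.8 CPM, the others at least 71.8, 0.879), Ccne2 in control 3 (55 CPM, at least 62.3, 0.864), Tap1 in control 1 (314 CPM, at most 257.5, 0.938) and Asns in formate 3 (138 CPM, at least 171, 0.947). The mitochondrial share stood apart in control 2 (0.566%, the others at most 0.438%, 0.841). CD4 T cell markers did in formate 1 (22.1 CPM, at most 13.1, 0.977), NK and innate lymphoid markers in control 1 (17.7 CPM, at most 8.30, 0.837), and myeloid and dendritic markers in control 1 (189 CPM, at most 111, 0.839) and formate 1 (167 CPM, at most 106, 0.934). Control 1 and formate 1 carry neighbouring codes, 10 and 11.

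The first pattern is the 1711 genes called with the pairs as a block, for which only 8 splits part all 4 pairs, too few for a share under 0.05; the real one was 1 of 8 with as many calls, and the highest other gave 1. A trend with transcript length and a difference in depth are argued against, because 98.071% of calls stayed past the threshold with the same sign after length offsets and 93.98% after thinning to the smallest library. A GC trend stays open for part of the calls: 65.634% stayed after GC offsets, between the bounds set in advance, and the change correlated with GC content across genes (Spearman correlation -0.258; genes are not independent replicates). Of the 588 calls that GC offsets ended, 226 shrank by more than 1 SE (Klrd1 from 0.29 to 0.07, SE 0.06 in both), and for these, effects of formate and GC-linked differences between libraries cannot be told apart. The other 362 moved by at most 1 SE (Srr from 0.46 to 0.45, SE 0.14 in both). Their lost calls alone do not tell whether a GC trend had a part, because the SE measures the spread between libraries and not the error of the GC correction. Over all 588 the median size of the log2 change went from 0.20 to 0.15.

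Without the pairs, the count of 1 gene was matched by 4 of the 35 splits, so chance cannot be excluded for the count, and a count of 1 says little about the gene itself. Cth, that gene, had log2 changes of 1.35, 1.66, 1.05 and 1.27 in the pairs of codes 1, 7, 10 and 13 (paired edgeR SE 0.08, adjusted p = 2.37e-06). Its adjusted p was 0.00227 with the library set as a term (edgeR) and 0.000189 with the pairs as a random effect (limma-voom). The highest other split gave 4882 genes and parts codes 10 to 14 from codes 1 to 8, which points to the structure of the library sets. The 5 lists called without pairs were matched by 26 of 35 splits (highest other 15), so chance cannot be excluded for them either; with the pairs, 1 of 8 splits gave as many lists as the real 14, the highest other gave 10, and 8 splits are too few for a share under 0.05.

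The second pattern is the higher level of mitochondrially encoded transcripts with formate. Reads moved between these genes and their nuclear copies are argued against, since genes and copies together were higher in 4 of 4 pairs (folds of 1.38, 1.3001, 2.13 and 1.32 for codes 1, 7, 10 and 13). A loss of cytoplasmic mRNA, which leaves nuclear and mitochondrial RNA, may account for it, but the test does not decide this. The 21 genes with detained introns had a median paired change of 0.10, with 8 higher and 0 lower. That was at percentile 99.99 of 10000 random lists matched on expression, which treat genes as independent. Genes of this kind were taken up because 5 others stood among the calls, so their direction was partly set by these data. Gene counts also do not separate nuclear isoforms from spliced mRNA. With the GC trend removed the median was 0.06, at percentile 99.97. A change in mitochondrial transcription with formate stays open too, no test here separates it from such a loss, and such a loss is not excluded for the lists with lower genes either.

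The third pattern is that ATF4 target changes differed between pairs. The list mean was 6.17, 5.99, 5.26 and 5.46 log2 CPM in controls 1 to 4 and 6.05, 6.05, 5.94 and 5.99 in formate libraries 1 to 4, a ratio of SDs of 0.12558 (0.05 over 0.43). Random lists matched on expression had a median ratio of 0.946 (central 95% from 0.262 to 3.26). Genes in general thus did not spread less among formate libraries. The ratio does not decide on a difference between library sets in all genes, because one shared by both groups leaves it near 1. PC1 (51.2% of variance) followed the library sets, and the split that parts them called 4882 genes. The ATF4 list lay at percentile 0.27 of the random lists, but it was taken up for this pattern, so that value is no separate support. An edgeR interaction with the library set had a raw p under 0.05 for 5.06% of 13299 genes, about the share chance gives. With 8 libraries that fit has little left to estimate the spread, so the share does not decide the question. The hypothesis that formate libraries share one level while controls start from different ones was written after the values were seen; it cannot be told apart from a chance pattern, because the list was taken up for this pattern out of 41 lists and 41 times that percentile is 11.1. The interaction with the library set, which is not one of the study's groups, passed for 9 genes by edgeR (673 raw p under 0.05), among them Lars2, Slc6a9, Slc7a11, Gpt2, Clic4, Glod4, Vegfa and Aldh18a1, and for 1 of 25 ATF4 list genes (18 with a raw p under 0.05).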

How the results depend on the processing

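The library set as a term, each set alone, the random effect, the swaps within pairs for PC1 and all alternatives of the paired fit were chosen after seeing the data, and the others before. Where a result changed, the cause was not tested unless fewer samples were used. Without pairs the count of genes stayed at 1 with RLE, upper quartile, library size only, no filter, the CPM filter, limma-voom, non-robust dispersion, the 1.2-fold minimum and the library set as a term. It became 21 with DESeq2 (11 higher, 10 lower), 1711 with the replicate block (711 and 1000), 462 with the pairs as a random effect (252 and 210), and 0 (0 higher) by edgeR within codes 1 to 8 (601 raw p under 0.05) or within 10 to 14 (599). Leaving out each library gave 0 to 1 genes (0 to 1 higher). The 5 lists became 0 with an estimated correlation or fry and 14 with the block, and 4 to 11 leaving out each library; of the 5, 4 kept their call without control 1 or 2 and 3 without formate 3 or 4, where glycolysis lost it each time and the serine list without formate 3 or 4. The effector list (median 0.076, leave-one-out 0.035 to 0.11) passed with the block (0.0392, but 0.838 with an estimated correlation and 0.225 by fry). The PC1 exact permutation p was 0.125 once the replicate block was removed, the smallest that the 16 swaps within pairs allow.

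With the replicate block, the 1711 genes became 6 against a 1.2-fold minimum (5 and 1), 337 without codes 1 and 2 (160 and 177), 722 without 7 and 8 (303 and 419), 1371 without 10 and 11 (556 and 815) and 502 without 13 and 14 (224 and 278). Higher calls became 422 with GC offsets, and lower calls 539 with library size only and 1532 with length offsets. Of 76 named genes called with the block, 67 kept the call with GC offsets, 70 with library size only, 71 without robust estimation and all 76 with RLE, length offsets or thinning. The 14 paired lists became 0 with an estimated correlation or fry (which called 1 other list), 7 without codes 1 and 2 and 9 without 7 and 8. The effector list lost its call with an estimated correlation or fry (median 0.076), without 7 and 8 (0.093), 10 and 11 (0.10) or 13 and 14 (0.056), and with the GC trend removed (0.075). The camera direction of the NRF2 list turned without 7 and 8 (median 0.014). In the unpaired fit it turned without control 3 (median 0.014) or formate 4 (0.048), and that of the effector list without control 2 (0.061). Among the lists, the block changed no call other than those given with it. DESeq2 gave no adjusted p for Nqo1 with the block.

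Single genes that turned were not called in the fit concerned. Unpaired, Cd8a had 0.018 (upper quartile), 0.034 (library size only), 0.010 (CPM filter) and 0.00773 (codes 1 to 8), and ND3 had 0.0048 (library size only). Within codes 10 to 14 Hmox1 had -0.015, Mthfd2 -0.18, ND3 0.13, Shmt2 -0.11 and Slc7a11 -0.23, and within 1 to 8 Tnf had -0.023. With the block, Cd8a had 0.017 (upper quartile), 0.033 (library size only), 0.0092 (CPM filter) and 0.023 (without 10 and 11), and Il2ra had -0.015 (without 7 and 8), -0.00449 (without 10 and 11) and -0.012 (GC offsets). Mthfd2 had -0.038 without 1 and 2 and -0.037 without 7 and 8, ND3 0.00566 with library size only and 0.088 without 1 and 2, and Shmt2 -0.00879 without 1 and 2.

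Leaving out each library in the unpaired fit gave log2 changes of -0.054 to 0.24 for Ifng, -0.021 to 0.18 for Gzmb, -0.044 to 0.14 for Prf1, -0.11 to 0.20 for Tnf, -0.23 to 0.012 for Tbx21, -0.46 to 0.037 for Il12rb2 and -0.080 to 0.34 for Pdcd1. It gave -0.0098 to 0.048 for Il2ra, -0.053 to 0.068 for Cd8a, -0.024 to 0.13 for Mthfd2, -0.0036 to 0.14 for Shmt2, -0.045 to 0.51 for Ccl4, -0.010 to 0.65 for Klrd1 and -0.47 to 0.11 for Bhlhe40. It gave -0.52 to 0.033 for Fdps, -0.83 to 0.027 for Fads2, -0.55 to 0.13 for Scd2, -0.50 to 0.11 for Bcl2l1 and -0.12 to 0.059 for ND3. List medians ranged from -0.36 to -0.023 (glycolysis), -0.14 to -0.080 (TCA cycle), 0.011 to 0.075 (NRF2), -0.021 to 0.15 (ribosomal proteins), -0.32 to 0.064 (ribosome biogenesis) and -0.24 to 0.068 (cholesterol synthesis), and the difference in the share of the top 10 genes from -0.39 to 0.054 percentage points. Evening out depth between libraries changed the count little: thinning to the smallest library called 1747 of 12939 tested genes with the block. Whether depth in general limits the calls was not tested.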

Other observations

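Interferon gamma response genes moved both ways with formate in the paired edgeR fit: of 24 tested members 5 rose, 4 fell and 15 did not pass (6 and 5 adjusted over the list alone), and the list did not pass (median -0.02, paired camera direction up, adjusted p = 0.934). Iigp1 (0.23, 0.0203) and Ifi47 (0.22, 0.00784), which encode interferon-induced GTPases, rose. Tap1 (the peptide transporter, -0.18, 0.0309) and Psmb8 (an immunoproteasome subunit, -0.15, 0.0410) fell. The 4 genes were chosen after their values were seen. With GC offsets Iigp1 had 0.09 (adjusted p = 0.347), Tap1 -0.14 (0.0670) and Psmb8 -0.13 (0.0681), so these 3 calls were lost. All 3 were also lost without codes 1 and 2 (0.125, 0.0738 and 0.140), without 7 and 8 (0.0694, 0.0774 and 0.129) and without 13 and 14 (0.0770, 0.102 and 0.0709). Tap1 and Psmb8 were lost without 10 and 11 too (0.102 and 0.118), hence without any 1 pair, and with upper quartile scaling (0.0523 and 0.0727), library size only (0.0674 and 0.0934) and no robust estimation (0.0558 and 0.0640), and Psmb8 with the CPM filter (0.0518) and limma-voom (0.0501). None of the 4 passed against a 1.2-fold minimum. The Ifi47 call was lost without 1 and 2 (0.0699) and without 13 and 14 (0.0502).

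The 27 lists that passed in neither fit had camera adjusted p values from 0.0775 to 0.973 unpaired and from 0.181 to 0.951 paired. The numbers that follow are members higher and lower with the pairs as a block (edgeR), and in brackets those adjusted over the list alone. Over all 13299 tested genes 711 were higher and 1000 lower in that fit, so a list with few calls may hold no more than the overall share. Naive and memory genes had 1 and 3 of 20 (1 and 3), inhibitory receptor genes 1 and 0 of 14 (1 and 0), activation genes 2 and 2 of 14 (2 and 2), immediate early genes 1 and 3 of 19 (1 and 3) and type 2, type 17 and regulatory genes 2 and 0 of 17 (3 and 0). Other antioxidant enzymes had 0 and 3 of 19 (2 and 4), pyrimidine synthesis genes 0 and 2 of 12 (0 and 2), heat shock genes 1 and 3 of 14 (2 and 6), unfolded protein response genes 1 and 1 of 15 (1 and 1), fatty acid oxidation genes 0 and 2 of 17 (0 and 2), hypoxia targets 1 and 1 of 16 (2 and 4), p53 targets 2 and 0 of 16 (2 and 0) and NF-kB targets 3 and 4 of 16 (3 and 6). Type I interferon genes had 0 and 0 of 21 (0 and 0), homing receptor genes 0 and 3 of 13 (0 and 3), chromatin enzymes 0 and 2 of 16 (1 and 4), CD8 identity genes 0 and 1 of 12 (1 and 1), ATF4 targets 0 and 1 of 25 (0 and 0) and methionine and polyamine genes 1 and 0 of 15 (4 and 2). B cell markers had 1 and 0 of 10 (1 and 0), CD4 T cell markers 0 and 0 of 4 (0 and 0), NK markers 0 and 0 of 4 (0 and 0) and myeloid markers 0 and 0 of 10 (0 and 0). The methionine and polyamine member past over all genes was Cth.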
